A study of Danio rerio with 12 samples.

How the data were processed

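Liver RNA of 12 libraries from transgenic zebrafish was analysed, 3 each for DMSO, TDCIPP, DOX and TDCIPP+DOX. Per the labels, RNA was taken with Trizol and libraries were made with the NEBNext Ultra kit. The deposited table holds raw counts of reads per gene, with 1 column per library and no normalization. The authors aligned reads with HISAT; its version, the counting program, the genome build and the annotation are not given in the sources used here. The same deposited table holds an adjusted p-value and a call per gene for 4 of the authors' own comparisons (p-value as unit), whose tool is not named. These were used only for the count of shared calls. Each of the 12 count columns was matched to 1 library by its header, and 0 columns were left over.

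The table has 34028 genes, 31895 of them Ensembl genes and 2133 gene models without an Ensembl entry. Gene names came from the table. A reference table of gene identifiers and symbols named 5571 of 8443 genes with no name, gave symbols to 17 of 19 genes whose names a spreadsheet had turned into dates, and replaced 1489 clone names.

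Counts were fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, TMM factors, default low count filter by group), as 1 model with a mean per group over all 12 libraries, no replicate block and 8 residual degrees of freedom. The filter left 19160 genes. The common dispersion was 0.297. The 5 comparisons between groups and the interaction, which is the effect of TDCIPP with DOX less its effect without DOX, were tested 2-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Adjusted p-values of genes are edgeR's. Where a group had 0 reads for a gene, the fold is a lower bound from a floor of 3 reads over the group, which covers counting error only. The fits were tested on simulated data of the same depth, with the spread of each gene pooled over the groups.

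The 34 gene lists of pathways and cell type markers matched 976 of 1004 entries, 943 distinct genes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. List medians are medians of edgeR log2 fold changes. Members past the test are counted over all genes and adjusted over the list alone. The oocyte markers were added after the data were examined.

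The lists, tests, comparisons and the rule for naming genes were fixed before the data were examined. The level of 1 gene fixed beforehand is not reported here. The rule named from each list that was called or had at least 3 members past the threshold up to 4 members by adjusted p, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups. It left out clone names. It also named il1b, tnfa, cxcl8a, mpx, mmp9, saa, dusp6, ccna2, pcna and mki67 in any comparison. Not every gene that the rule names is printed.

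Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0 in place of edgeR, only the libraries of the groups compared, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library in turn. Alternatives for normalized values were not needed, since the table holds counts. Scaling by library totals and leaving out the 4 libraries with ovary or intestine markers (DMSO replicate 3, TDCIPP replicate 1, DOX replicate 3 and TDCIPP+DOX replicate 3) were added after seeing the data. The labels give no sequencing batch, date, sex or hour of collection, so none could be fitted.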

Results

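Liver RNA was sequenced from zebrafish of a transgenic line at 3 months of age. The 12 libraries fell into 4 groups of 3: DMSO, the solvent control, TDCIPP, DOX, and TDCIPP together with DOX (TDCIPP+DOX). TDCIPP is tris(1,3-dichloro-2-propyl)phosphate, an organophosphate flame retardant. The labels do not spell out DOX. The series title sets the question of whether TDCIPP promotes liver tumours and whether inflammatory responses take part. Each library held 28621536 to 40877342 reads assigned to genes, and 19160 genes were tested. No source used here says that the 3 libraries of a group came from separate fish, so p-values measure the spread between libraries, which may be technical in part. The biological coefficient of variation was 54.5%. In simulated data of this depth and spread, 70% of genes changed 4-fold and 0% of genes changed 2-fold were recovered between TDCIPP and DMSO. Between TDCIPP+DOX and DOX the shares were 54% and 10%. The changed genes were drawn only from those with a mean over 5 CPM, and genes were simulated independently. The shares therefore do not cover genes of lower level, several of which are described below. Each gene was simulated with the same spread in all groups. In the data DOX replicate 3 stood apart, with an r of log2 CPM of 0.818 and 0.811 with DOX replicates 1 and 2. Between these the r was 0.944. The shares do not allow for that library.

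Transcripts of the vitellogenins, the yolk precursors that livers of egg-laying fish secrete, took the largest share of reads. They made up 40.33% ± 5.23 (SD, n = 3) of reads in DMSO, 31.72% ± 5.47 in TDCIPP, 27.06% ± 6.93 in DOX and 14.07% ± 3.7 in TDCIPP+DOX. Levels below are CPM, reads scaled by TMM to a common library size, given as mean ± SD over 3 libraries, and fold changes come from edgeR's model with the SE of the log2 value. Some vitellogenin genes are near-identical copies, so reads may be split between those. Scaling by library totals in place of TMM moved the median log2 fold change of all genes from 0.02 to 0.39 for TDCIPP against DMSO, from 0.12 to 0.83 for DOX against DMSO, from -0.08 to 0.23 for TDCIPP+DOX against DOX. The median moved from 0.1 to 1.11 for TDCIPP+DOX against DMSO and from -0.01 to 0.64 for TDCIPP+DOX against TDCIPP. Directions below are relative to the TMM reference.

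The genes were grouped by 34 lists of pathways and cell type markers fixed before the data were examined. Camera with a preset correlation called 13 lists for TDCIPP against DMSO (8 higher, 5 lower), 15 for DOX against DMSO (5 higher, 10 lower) and 25 for TDCIPP+DOX against DOX (18 higher, 7 lower). It called 11 for TDCIPP+DOX against DMSO (6 higher, 5 lower), 7 for TDCIPP+DOX against TDCIPP (4 higher, 3 lower) and 16 for the interaction (11 higher, 5 lower). With a correlation estimated from the libraries camera called 0 lists in each comparison, so no list call below holds in camera with that setting. Fry, which asks whether the genes of a list move one way on balance, called 4, 4, 8, 11, 4 and 1 lists in the same order. Which lists fry and camera both called is not given here.

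Transcripts of other organs were present. The exocrine pancreas gene prss1 lay between 9.24 and 550.57 CPM in the 12 libraries, above 100 in 9 of them, whereas intestine transcripts peaked in 3 libraries and oocyte transcripts in 1. The fatty acid binding protein of intestine, fabp2, stood at 55.69 CPM in DMSO replicate 3, 46.83 in TDCIPP replicate 1 and 105.76 in TDCIPP+DOX replicate 3. In the other libraries it lay between 0.2 and 8.73. The oocyte gene buc, which organises the Balbiani body, stood at 205.21 CPM in DOX replicate 3 and at most at 22.61 elsewhere. All 14 oocyte markers measured, a set chosen after the libraries had been seen, were at least 3.3 times as high in DOX replicate 3 as in any other library (median 9.35 times).

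**Figure D1:**
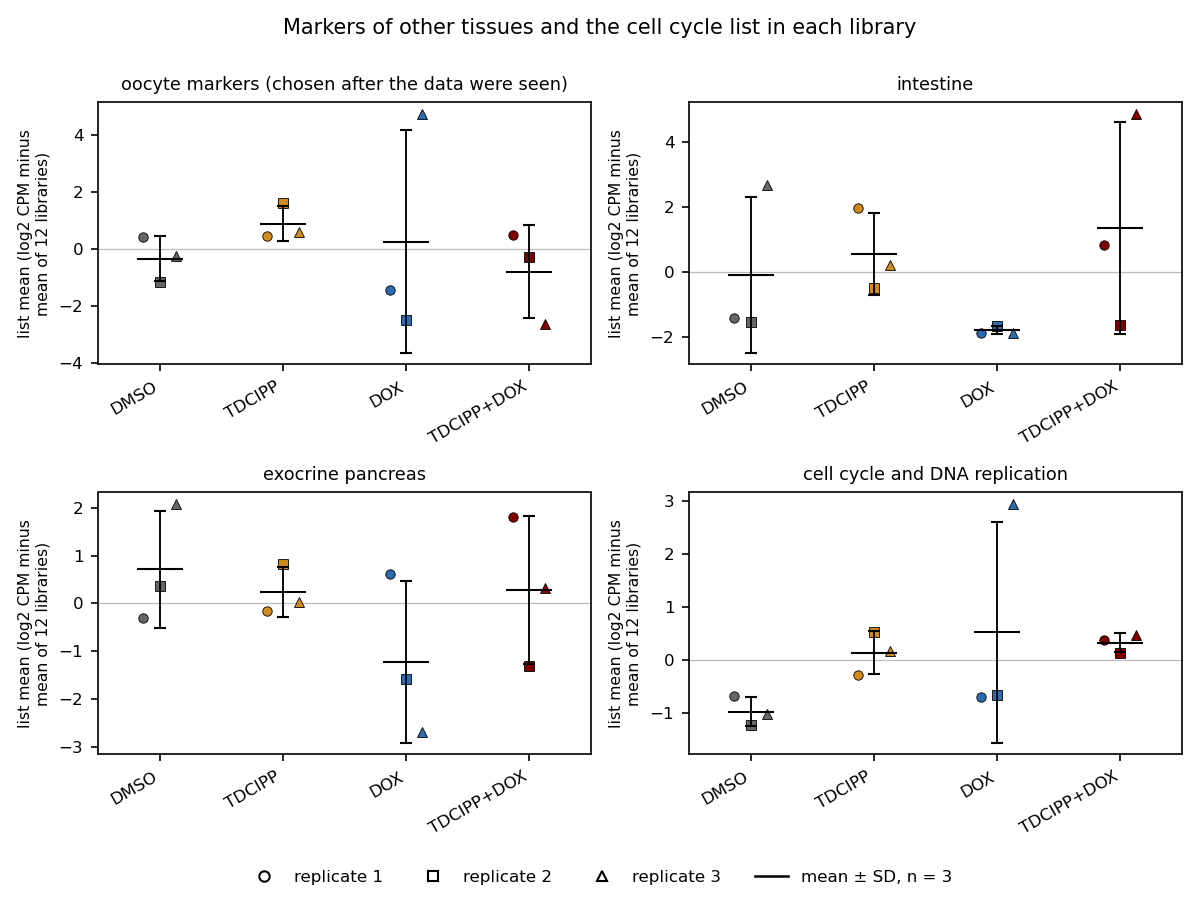
Mean of 4 gene lists in each library, as log2 CPM minus the mean over the 12 libraries on the y axis and the 4 groups on the x axis. Points are libraries, shaped by replicate number, and bars give the mean ± SD (n = 3). Oocyte markers stood at 4.73 and the cell cycle list at 2.93 in DOX replicate 3, and the intestine list at 4.85 in TDCIPP+DOX replicate 3.

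TDCIPP was set against DMSO to show what the compound did without DOX. Genes of inflammatory signalling lay higher in the TDCIPP libraries as a group. The inflammatory cytokine and NF-kB list had a median log2 fold change of 1.66 over 37 members (camera adjusted p = 5.35e-11; adjusted p = 0.0834 with an estimated correlation). In edgeR 0 of the 37 passed over all genes, 20 were higher at an unadjusted p under 0.05, 18 rose when adjusted over the list alone, and DESeq2 called 10 higher. The neutrophil chemokine cxcl8a stood at 6.99 ± 1.38 CPM against 0.787 ± 0.0766, an 8.85-fold difference (edgeR adjusted p = 0.059). The T cell chemokine ccl19a.1 stood at 14.8 ± 3.56 against 3.91 ± 0.437, the NF-kB inhibitor nfkbiaa at 34.6 ± 13.9 against 8.46 ± 4.57, and il1b, interleukin 1 beta, at 4.77 ± 0.828 against 1.01 ± 0.676. The cytokine gene tnfa stood at 0.845 ± 0.742 against 0.245 ± 0.0645 (edgeR adjusted p = 0.617). The per-library means of the list lay between 0.53 and 1.09 in TDCIPP and between -0.9 and -0.34 in DMSO, and without TDCIPP replicate 3 the list's median was 1.08.

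Neutrophil and macrophage markers lay higher as lists. The neutrophil list had a median log2 fold change of 2.33 (camera adjusted p = 1.76e-07; adjusted p = 0.313 with an estimated correlation). It had 0 of 12 members past edgeR's test over all genes, 8 past an unadjusted p of 0.05, 8 past it when adjusted over the list alone and 6 called higher by DESeq2. The collagenase gene mmp13a stood at 9.93 ± 1.66 CPM against 0.4 ± 0.0106, and cyba, a subunit of the phagocyte oxidase, at 27.2 ± 11.6 against 5.86 ± 2.85. The libraries overlapped for myeloperoxidase, mpx, at 3.16, 45.05 and 26.11 CPM in TDCIPP and 15.25, 27.54 and 1.34 in DMSO (edgeR adjusted p = 0.852). The gelatinase gene mmp9 stood at 3.63 ± 3.74 against 1.01 ± 1.22 (edgeR adjusted p = 0.664). The macrophage list had a median of 0.88 (camera adjusted p = 3.5e-05; adjusted p = 0.531 with an estimated correlation). It had 0 of 19 members past edgeR's test over all genes, 7 past an unadjusted p of 0.05, 7 when adjusted over the list alone and 3 called higher by DESeq2. Its median was 1.55 without DMSO replicate 3 and 0.31 without TDCIPP replicate 3. Its member grna, a progranulin gene, stood at 73.2 ± 33.8 against 20.4 ± 5.38. The B cell list was higher as well (median 1.41, camera adjusted p = 0.00286; adjusted p = 0.446 with an estimated correlation; median 0.79 without TDCIPP replicate 3). The T and NK cell list was not called, with a median of 0.13 (camera adjusted p = 0.514). The acute phase gene saa reached 1874.41 CPM in TDCIPP replicate 1 and 6.46 to 12.48 in the other TDCIPP libraries, so its group mean of 631 ± 1080 rests on 1 library. That library also held intestine transcripts. In DMSO replicate 3 and TDCIPP+DOX replicate 3, where the intestine gene fabp2 stood higher still, saa stood at 1.43 and 0.13 CPM.

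Genes of gluconeogenesis and amino acid catabolism lay lower. Their list had a median of -0.42 over 32 members (camera adjusted p = 2.73e-06; adjusted p = 0.32 with an estimated correlation). In edgeR 0 passed over all genes, 8 were lower at an unadjusted p under 0.05, 5 fell when adjusted over the list alone, and DESeq2 called 4 lower. The arginase arg2 stood at 33.7 ± 15.2 CPM against 265 ± 62.2, and the gluconeogenic enzymes pck1 and g6pca.2 at 4.61 ± 6.13 against 403 ± 282 and at 102 ± 85.4 against 1600 ± 637. On the glycolysis list (median 0.58, camera adjusted p = 0.0109; adjusted p = 0.32 with an estimated correlation), 0 of 30 passed over all genes in edgeR, 9 were higher and 1 lower at an unadjusted p under 0.05, 6 rose when adjusted over the list alone and DESeq2 called 4 higher. Its member pfkfb3, which makes the activator of phosphofructokinase, stood at 8.77 ± 4.93 against 0.771 ± 0.53. The median of the glycolysis list was 1.01 without DMSO replicate 3 and 0.29 without TDCIPP replicate 3.

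The cell cycle and DNA replication list was higher, with a median of 1.1 and 60 of 62 members above 0 (camera adjusted p = 2.45e-07; adjusted p = 0.695 with an estimated correlation). In edgeR 0 of the 62 passed over all genes or when adjusted over the list alone, 3 were higher at an unadjusted p under 0.05, and DESeq2 called 0. The oocyte markers stood higher in TDCIPP as well, with per-library means of 0.47, 1.61 and 0.59 against 0.41, -1.18 and -0.25. Markers of the endocrine pancreas were lower (median -2.15, camera adjusted p = 1.59e-06; adjusted p = 0.255 with an estimated correlation). In edgeR 0 of 7 passed over all genes, 4 were lower at an unadjusted p under 0.05, 3 fell when adjusted over the list alone and DESeq2 called 3 lower. Insulin, ins, stood at 0.03 to 0.55 CPM in TDCIPP and 1.61 to 11.44 in DMSO (edgeR adjusted p = 0.244). The median of these markers was -3.66 without TDCIPP replicate 2 and -4.49 without TDCIPP replicate 3.

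Single genes past the threshold were few: 2 rose and 6 fell. The clock gene per2 rose 4.45-fold (log2 2.15 ± 0.23, edgeR adjusted p = 0.0102). Levels of clock genes, here and below, depend on the hour of collection, which the labels do not give. The glutamine synthetase gene glula fell by 3.98 ± 0.5 on the log2 scale (edgeR adjusted p = 0.0299), from 149 ± 73.5 to 9.41 ± 5.34 CPM. The mitochondrial carrier gene slc25a25a fell from 414 ± 168 to 28.3 ± 1.02 CPM, the growth factor gene fgf6a from 7.15 ± 3.02 to 0.535 ± 0.158, and eif4ebp3, of the family that holds back translation initiation, by 1.79 ± 0.24 on the log2 scale (edgeR adjusted p = 0.0484, 0.0299 and 0.0435). Outside the rule for naming genes, and picked after their values were seen, Novel00094, a gene model without an Ensembl entry, rose by 3.27 ± 0.34 on the log2 scale, and si:dkey-22f5.9 and si:dkey-62o19.6 fell by 1.85 ± 0.24 and 2.79 ± 0.39 (edgeR adjusted p = 0.0102, 0.0338 and 0.0477). An unadjusted p under 0.05 was met by 1920 genes. Without DMSO replicate 2, DMSO replicate 3 or TDCIPP replicate 2 edgeR called 0 genes, without TDCIPP replicates 1 and 3 it called 2 and 3, and without DMSO replicate 1 it called 18. DESeq2 called 414, no filter on low counts gave 17, the fit without the 4 libraries with ovary or intestine markers gave 0, and library totals in place of TMM gave 4 higher and 2 lower. Of the 5 named genes that passed, 0 passed in every fit that left out 1 library, and DESeq2 called all 5.

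**Figure D2:**
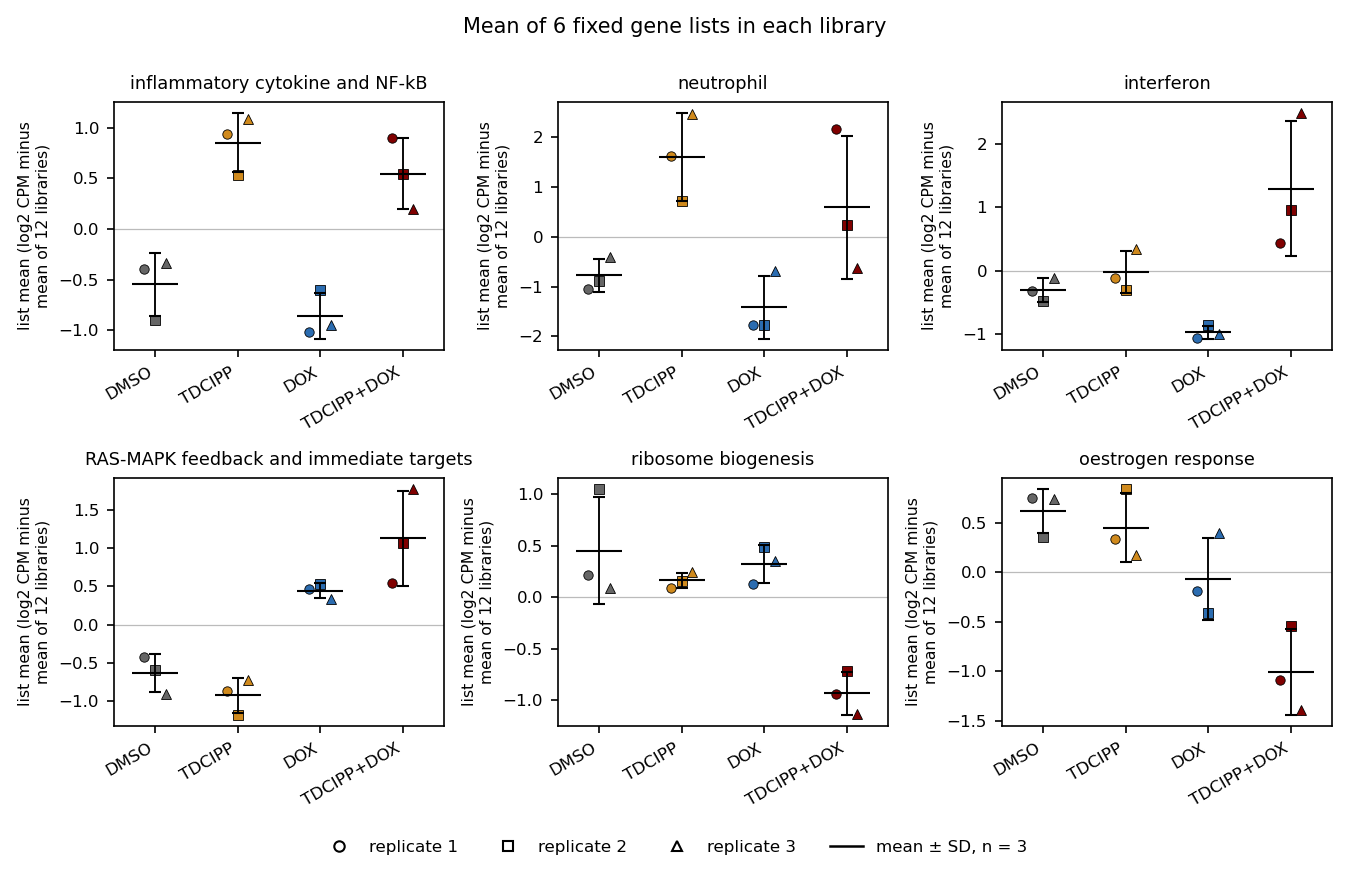
Means of 6 fixed gene lists in each library, as log2 CPM minus the mean over the 12 libraries (y axis), by group (x axis). Points are libraries and bars the mean ± SD (n = 3). The inflammatory list lay between 0.2 and 1.09 in the 6 libraries with TDCIPP and between -1.02 and -0.34 in the 6 without.

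DOX was set against DMSO to show the effect of DOX alone in this line. Here 753 genes were higher and 562 lower. The largest rises included esm1, an endothelial proteoglycan gene, from 0.807 ± 0.321 to 376 ± 308 CPM (log2 8.86 ± 0.97, edgeR adjusted p = 0.00379), the collagen-binding integrin gene itga2.1 from 0.106 ± 0.143 to 17.6 ± 15.5 (edgeR adjusted p = 0.00704) and the phospholipid transfer protein gene pltp from 1.61 ± 0.85 to 270 ± 307 (edgeR adjusted p = 0.00992). The leptin gene lepa had 0 reads in DMSO and 35.9 ± 37.9 CPM in DOX, at least 780-fold higher when 3 reads over the DMSO group are taken as the floor. Of the RAS-MAPK feedback and immediate target list, 6 of 34 members rose and 0 fell (7 rose when adjusted over the list alone), and the list lay above other genes with a median of 0.93 (camera adjusted p = 0.000544; adjusted p = 0.553 with an estimated correlation). Without DOX replicate 3 that median was 0.53. The immediate early gene egr2a rose from 1.81 ± 1.54 to 43 ± 19.6 CPM, the MAP kinase phosphatase gene dusp4 from 2.55 ± 0.381 to 19.3 ± 6.88, and the AP-1 gene fosl1a from 0.658 ± 0.413 to 4.05 ± 2.52 (edgeR adjusted p = 0.00842, 0.00992 and 0.0294).

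Genes of lipid metabolism changed in both directions. The glycolysis list was higher (median 0.67, camera adjusted p = 0.0446), with 12 of 30 members higher and 3 lower at an unadjusted p under 0.05. DESeq2 called 6 of them higher and 2 lower. The list was not called without DMSO replicate 1 (median 0.64, camera adjusted p = 0.0743) or DOX replicate 2 (median 0.56, camera adjusted p = 0.188). The hexokinase gene gck, the liver glucokinase, rose from 1.85 ± 1.78 to 275 ± 117 CPM (edgeR adjusted p = 0.0214), the fatty acid synthase gene fasn from 64.6 ± 7.78 to 632 ± 413 (edgeR adjusted p = 0.00992) and its regulator srebf1 from 12.7 ± 0.345 to 40.6 ± 7.73 (edgeR adjusted p = 0.0155). On the fatty acid synthesis list 5 of 26 members rose and 4 fell (6 and 5 when adjusted over the list alone), among the latter acacb, the mitochondrial acetyl-CoA carboxylase, from 107 ± 6.05 to 26 ± 9.99 CPM (edgeR adjusted p = 0.00577). The list as a whole was not called (camera adjusted p = 0.554). The sterol synthesis list had 4 of 25 members up, including acat2 and mvda, and a median of 1.24 (5 rose when adjusted over the list alone; camera adjusted p = 0.000213; adjusted p = 0.553 with an estimated correlation). Without DOX replicate 2 the sterol median was 0.64. On the fatty acid oxidation list 3 of 34 fell, over all genes and when adjusted over the list alone, among them cpt1ab, a carnitine palmitoyltransferase, from 38.3 ± 2.58 to 8.46 ± 6.03 CPM, and pdk2a, a pyruvate dehydrogenase kinase. That list had a median of -0.46 (camera adjusted p = 4.97e-05; adjusted p = 0.553 with an estimated correlation), which was 0.2 under library totals, where the median of all genes was 0.83 and the list was not called (camera adjusted p = 0.125). The ER stress list had a median of 1.16 (camera adjusted p = 0.000203; adjusted p = 0.553 with an estimated correlation). It had 0 of 36 members past edgeR's test over all genes, 21 higher and 2 lower at an unadjusted p under 0.05, 20 higher and 1 lower when adjusted over the list alone and 15 called higher by DESeq2.

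Among stress and hormone genes, the cystine transporter gene slc7a11 rose from 0.0754 ± 0.0945 to 8.09 ± 7 CPM and the thioredoxin gene txn from 72.3 ± 36.8 to 235 ± 72.2, and keap1a, the inhibitor of Nrf2, fell from 26.4 ± 2.02 to 10.6 ± 2.34 (edgeR adjusted p = 0.00992, 0.0267 and 0.00957). On the Nrf2 list 4 of 33 members rose and 1 fell, 5 and 3 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.307). The glucocorticoid-responsive genes klf9 and tsc22d3 fell from 68 ± 34.7 to 4.82 ± 2.62 and from 463 ± 253 to 110 ± 65 CPM (edgeR adjusted p = 0.00687 and 0.0361). The gene klf9 was also read with the clock genes, so the caveat on the hour of collection covers it. The cortisol-inactivating enzyme gene hsd11b2 fell from 84.9 ± 38.8 to 2.48 ± 0.66 and the cytokine signalling inhibitor gene cishb from 13.5 ± 1.56 to 0.711 ± 0.352 (edgeR adjusted p = 0.00379 for each). On the xenobiotic metabolism list 2 of 53 members rose and 4 fell, 4 and 9 when adjusted over the list alone. Its median was -0.4 (camera adjusted p = 0.0288, or 0.553 with an estimated correlation). Under library totals it was 0.228 against 0.83 for all genes, and the list was not called (camera adjusted p = 0.0531). The median was -0.2 without DOX replicate 3, the library with oocyte transcripts, and -0.28 without DMSO replicate 3, and the list was then not called (camera adjusted p = 0.409 and 0.0602). It was -0.66 without DOX replicate 1, and -0.179 without the 4 libraries with ovary or intestine markers (camera adjusted p = 0.717). Of its members cyp1a, the dioxin-inducible monooxygenase, fell from 543 ± 89.3 to 214 ± 84.2 (edgeR adjusted p = 0.0294) and the sulfotransferase gene sult1st1 rose from 3.37 ± 2.51 to 25.8 ± 10.8 (edgeR adjusted p = 0.0117). Of 32 clock genes 8 rose and 9 fell, 8 and 13 when adjusted over the list alone. Among them, per2 rose from 2.23 ± 0.152 to 32.4 ± 8.08 CPM (log2 3.86 ± 0.24, edgeR adjusted p = 8.63e-05) and the D-box factor gene dbpb fell from 46.2 ± 13.4 to 6.5 ± 2.76 (edgeR adjusted p = 0.00379). The clock list as a whole was not called (camera adjusted p = 0.056). It was called lower without DMSO replicate 1 or 2 or DOX replicate 1 or 2 (medians -0.5, -0.56, -0.61 and -0.57). The oestrogen response list, which holds the vitellogenins, had a median of -1.03 and a mean of 0.14 (camera adjusted p = 0.000737; adjusted p = 0.553 with an estimated correlation). Of its members 0 of 15 were past edgeR's test over all genes, 7 lower and 3 higher at an unadjusted p under 0.05, 4 lower when adjusted over the list alone and 5 called lower by DESeq2.

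The cell cycle and DNA replication list had the highest median, 2.79, with 14 of 62 members up and 48 when adjusted over the list alone (camera adjusted p = 4.25e-08; adjusted p = 0.553 with an estimated correlation). The replication clamp gene pcna rose from 9.92 ± 3.06 to 53.7 ± 39.8 CPM and the helicase gene mcm5 from 3.73 ± 1.4 to 27.5 ± 23.1 (edgeR adjusted p = 0.0257 and 0.0226). The per-library means of the list were -0.7, -0.66 and 2.93, the last in the library with oocyte transcripts. Without that library the median was 0.46, 8 of 62 members passed and the list was not called (camera adjusted p = 0.0618), and the cyclin gene ccna2 turned from a log2 difference of 3.29 ± 1.3 (edgeR adjusted p = 0.143) to -0.885.

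Markers of some cell types other than hepatocytes lay lower in DOX than in DMSO. On the stellate and fibroblast list 4 of 25 fell, 7 when adjusted over the list alone (median -1.4, camera adjusted p = 1.37e-06; adjusted p = 0.553 with an estimated correlation), among them col1a2, a collagen gene, from 8.57 ± 2.88 to 1.91 ± 0.535 CPM (edgeR adjusted p = 0.0319). Of 7 endocrine pancreas markers 3 fell, 4 when adjusted over the list alone (median -3.12, camera adjusted p = 0.000213; adjusted p = 0.553 with an estimated correlation), with ins, insulin, from 6.58 ± 4.92 to 0.156 ± 0.245 (edgeR adjusted p = 0.0425). The erythroid, exocrine pancreas, intestine and endothelial lists were lower too, with medians of -1.35, -1.83, -2.57 and -0.58 (camera adjusted p = 6.37e-05, 5.92e-05, 0.00989 and 0.00989). The intestine and endothelial lists were not called without DMSO replicate 3 (medians -0.65 and -0.42, camera adjusted p = 0.239 and 0.0589) or DOX replicate 3 (medians -2.64 and -0.66, camera adjusted p = 0.0618 and 0.0689). The exocrine pancreas median was -0.65 without DMSO replicate 3 and -3.77 without DOX replicate 1. Without the 4 libraries with ovary or intestine markers the exocrine pancreas, intestine and endothelial lists were not called (medians -0.26, -0.435 and -0.399, camera adjusted p = 0.406, 0.4 and 0.241). Nor was the endothelial list under library totals (median 0.0885 against 0.83 for all genes, camera adjusted p = 0.0531). Across all genes 5099 met an unadjusted p under 0.05. The count of 1315 became 262, 405 and 209 without DMSO replicates 1, 2 and 3, 782 without DOX replicate 2, 684 without the 4 libraries with ovary or intestine markers, 97 when only the DOX and DMSO libraries were fitted, 822 without the filter on low counts and 2636 in DESeq2. With library totals 4802 genes rose and 231 fell. Of 32 genes named for this comparison that passed, 17 passed without any 1 library. The others were ins, gck, mcm5, pcna, col1a2, cpt1ab, srebf1, pdk2a, txn, tsc22d3, cyp1a, mvda, acat2, fosl1a and pltp.

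TDCIPP+DOX was set against DOX to show what TDCIPP added once DOX was given. The interferon list showed the highest median among lists of signalling and metabolism, 2.73, with 9 of 32 members up and 29 when adjusted over the list alone (camera adjusted p = 8.65e-17; adjusted p = 0.215 with an estimated correlation). The ubiquitin-like antiviral gene isg15 rose from 3.73 ± 1.35 to 35.7 ± 31.4 CPM, mxc and mxe, antiviral GTPases, from 0.601 ± 0.462 to 12.2 ± 8.38 and from 0.864 ± 0.233 to 6.32 ± 4.1, and gbp1, a guanylate binding protein gene, from 7.18 ± 1.57 to 24.2 ± 7.79 (edgeR adjusted p = 0.0421, 0.0439, 0.0333 and 0.0364). The per-library means of the list were 0.44, 0.96 and 2.48 in TDCIPP+DOX, against -1.05, -0.85 and -0.99 in DOX. The highest came from replicate 3, the library with the highest intestine markers, and without it the list's median was 1.71. Set against DMSO, the interferon list was lower in DOX (median -0.66, camera adjusted p = 0.00261; adjusted p = 0.553 with an estimated correlation) and was not called in TDCIPP (median 0.26, camera adjusted p = 0.179). The lower level in DOX was not called without DOX replicate 3 (median -0.57, camera adjusted p = 0.0635) or without the 4 libraries with ovary or intestine markers (median -0.286, camera adjusted p = 0.103). On the inflammatory cytokine and NF-kB list 5 of 37 rose, 12 when adjusted over the list alone (median 1.41, camera adjusted p = 1.43e-08; adjusted p = 0.195 with an estimated correlation). They included ccl19a.1, from 4.6 ± 2.3 to 36.6 ± 9.16 CPM, il1b, from 0.285 ± 0.291 to 4.66 ± 3.78, and the NF-kB subunit gene relb, from 4.87 ± 1.55 to 11.4 ± 1.84 (edgeR adjusted p = 0.0176, 0.0485 and 0.0451). The chemokine gene cxcl8a stood at 3.47 ± 0.353 against 0.984 ± 0.571 (edgeR adjusted p = 0.0563). The RAS-MAPK list had a median of 0.65 (camera adjusted p = 0.00847), with 5 of 34 members higher and 2 lower at an unadjusted p under 0.05. It was not called without DOX replicate 3 (median 0.54, camera adjusted p = 0.112) or TDCIPP+DOX replicate 3 (median 0.25, camera adjusted p = 0.194).

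Markers of most cell types lay higher: 12 of the 13 cell type lists were called, all but the thrombocyte list (camera adjusted p = 0.155). On the neutrophil list 1 of 12 rose, 6 when adjusted over the list alone (median 2.18, camera adjusted p = 0.000478; adjusted p = 0.369 with an estimated correlation). Without TDCIPP+DOX replicate 1 the neutrophil median was 0.98. On the macrophage list 2 of 19 rose, likewise 2 when adjusted over the list alone (median 1.06, camera adjusted p = 0.000255; adjusted p = 0.369 with an estimated correlation). The phagocyte oxidase gene ncf1 rose from 1.36 ± 0.645 to 12.7 ± 9.92 CPM, mpeg1.2, a perforin of macrophages, from 0.759 ± 0.354 to 7.81 ± 5.07, and the progranulin gene grna from 15.5 ± 0.332 to 54.5 ± 15.7 (edgeR adjusted p = 0.0464, 0.0364 and 0.0364). Myeloperoxidase, mpx, stood at 46.9 ± 38.8 against 0.558 ± 0.357 (edgeR adjusted p = 0.053). The stellate and fibroblast list had a median of 1.45 with 1 of 25 up, 8 when adjusted over the list alone (camera adjusted p = 1.23e-06; adjusted p = 0.369 with an estimated correlation). The intestine list had a median of 5.23 with 1 of 14 up, 12 when adjusted over the list alone (camera adjusted p = 0.000255; adjusted p = 0.378 with an estimated correlation). The median was 1.81 without TDCIPP+DOX replicate 3 and 1.38 (camera adjusted p = 0.13) without the 4 libraries with ovary or intestine markers.

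The other cell type lists called higher were endocrine pancreas (median 3.83), T and NK cell (1.55), erythroid (1.31), exocrine pancreas (1.26), B cell (1.2), biliary (0.98), endothelial (0.7) and hepatocyte (0.23). Their camera adjusted p values were 0.000598, 0.0163, 0.001, 0.00228, 0.00997, 0.000852, 0.000255 and 0.0456 in that order. Without DOX replicate 3 the B cell, erythroid, exocrine pancreas, biliary and hepatocyte lists were not called (medians 0.95, 0.97, 0.81, 0.85 and 0.05). Nor were the T and NK cell and hepatocyte lists without TDCIPP+DOX replicate 3 (0.29 and 0.24), the B cell and exocrine pancreas lists without TDCIPP+DOX replicate 1 (1.02 and 0.16), or the hepatocyte list without TDCIPP+DOX replicate 2 (0.26). The T and NK cell list was not called without DOX replicates 1 or 2 (1.4 and 1.14). The erythroid median was 0.73 without TDCIPP+DOX replicate 2 and the biliary median 0.54 without TDCIPP+DOX replicate 3. Without DOX replicate 1 exocrine pancreas was 3.17 and hepatocyte 0.46, and without DOX replicate 2 hepatocyte was 0.35. Without the 4 libraries with ovary or intestine markers the T and NK cell, exocrine pancreas, biliary and hepatocyte lists were not called (camera adjusted p = 0.146, 0.365, 0.0575 and 0.365), nor was the T and NK cell list under library totals (camera adjusted p = 0.0812).

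Genes of ribosome assembly fell together. On the ribosome biogenesis list 22 of 52 members fell and 0 rose, and 51 fell when adjusted over the list alone (median -1.3, camera adjusted p = 2.59e-30; adjusted p = 0.32 with an estimated correlation). The rRNA processing genes rrp12 and ftsj3 fell from 53.7 ± 8.7 to 20.7 ± 2.66 CPM and from 43.7 ± 10.9 to 15.4 ± 1.63 (edgeR adjusted p = 0.0322 for each), and mybbp1a, a nucleolar cofactor, from 41.7 ± 9.34 to 14.2 ± 2.85 (edgeR adjusted p = 0.0335). On the oestrogen response list 0 of 15 passed over all genes in edgeR, 11 were lower at an unadjusted p under 0.05, 7 fell when adjusted over the list alone and DESeq2 called 5 lower (median -1.39, camera adjusted p = 0.000692; adjusted p = 0.32 with an estimated correlation). On the sterol synthesis list 1 of 25 fell, 2 when adjusted over the list alone (median -1.09, camera adjusted p = 0.000393; adjusted p = 0.478 with an estimated correlation). Without DOX replicate 2 that median was -0.54 and the list was not called (camera adjusted p = 0.0518). On the fatty acid synthesis list 1 of 26 fell, likewise 2 when adjusted over the list alone (median -0.4, camera adjusted p = 0.0154; adjusted p = 0.369 with an estimated correlation). It was not called without DOX replicate 2 (median -0.41, camera adjusted p = 0.104), and its median was -0.76 without TDCIPP+DOX replicate 2. Falling genes of lipid metabolism included insig1, the sterol sensor partner, from 97.6 ± 49.8 to 18.6 ± 6.21 CPM, gpam, which starts glycerolipid synthesis, from 17 ± 6.36 to 4.2 ± 0.934, and acsl1b, an acyl-CoA synthetase gene, from 51.2 ± 18.9 to 8.01 ± 4.04 (edgeR adjusted p = 0.0364, 0.0322 and 0.0322). In all 136 genes rose and 267 fell, and 4675 met an unadjusted p under 0.05. This count rested on every TDCIPP+DOX library: edgeR called 0 genes without replicate 1, 2 or 3 of that group, 2 without DOX replicate 2 and 0 when only the 6 libraries compared were fitted. DESeq2 called 2102, the fit without a filter 143, the fit without the 4 libraries with ovary or intestine markers 57, and library totals gave 129 higher and 13 lower. Of 17 named genes that passed, 0 passed in every fit that left out 1 library, while DESeq2 called all 17.

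TDCIPP+DOX against DMSO gives the combined difference. It was the comparison with the most genes, 1021 higher and 1220 lower, with 5190 at an unadjusted p under 0.05. On the ribosome biogenesis list 44 of 52 fell, 49 when adjusted over the list alone (median -1.44, camera adjusted p = 1.16e-27; adjusted p = 0.351 with an estimated correlation). The helicase gene ddx21 fell from 888 ± 130 to 156 ± 2.06 CPM (log2 -2.51 ± 0.23, edgeR adjusted p = 0.000997). On the oestrogen response list 9 of 15 fell and 0 rose, over all genes and when adjusted over the list alone (median -1.9, camera adjusted p = 9.51e-07; adjusted p = 0.351 with an estimated correlation). The gene vtg6 fell from 31400 ± 6750 to 4030 ± 1410 CPM and vtg3 from 14100 ± 1970 to 2180 ± 767 (edgeR adjusted p = 0.0039 and 0.00404). The gene with the lowest adjusted p was eif4ebp3, which fell from 300 ± 50.6 to 10.8 ± 1.51 CPM (log2 -4.79 ± 0.28, edgeR adjusted p = 3.81e-05).

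On the RAS-MAPK list 11 of 34 rose and 1 fell, 16 and 2 when adjusted over the list alone (median 1.44, camera adjusted p = 2.23e-06; adjusted p = 0.351 with an estimated correlation). The phosphatase gene dusp6, a standard readout of ERK activity, rose from 28.8 ± 12.8 to 99.8 ± 45.7 CPM and fosl1a from 0.658 ± 0.413 to 12.2 ± 5.81 (edgeR adjusted p = 0.0215 and 0.00294). On the interferon list 11 of 32 rose, 19 when adjusted over the list alone (median 1.84, camera adjusted p = 4.52e-06; adjusted p = 0.443 with an estimated correlation). Without TDCIPP+DOX replicate 3 the interferon median was 0.91. On the inflammatory list 4 of 37 rose, likewise 4 when adjusted over the list alone (median 1.2, camera adjusted p = 0.000861; adjusted p = 0.351 with an estimated correlation), among them ccl19a.1 (9.36-fold) and cxcl8a (4.39-fold; edgeR adjusted p = 0.0018 and 0.0123). Without TDCIPP+DOX replicate 1 the inflammatory median was 0.61. On the neutrophil list 2 of 12 rose, likewise 2 when adjusted over the list alone (median 1.67, camera adjusted p = 0.0407; adjusted p = 0.711 with an estimated correlation). It was not called without DMSO replicate 1 or TDCIPP+DOX replicate 1 (medians 1.3 and 0.73, camera adjusted p = 0.0709 and 0.206), nor under library totals (camera adjusted p = 0.496). On the cell cycle list 4 of 62 rose over all genes and 0 when adjusted over the list alone (median 1.2, camera adjusted p = 4.75e-05; adjusted p = 0.774 with an estimated correlation). It was not called under library totals (camera adjusted p = 0.31). The proliferation marker mki67 stood at 7.37 to 15.8 CPM against 1.45 to 1.93 (edgeR adjusted p = 0.0532). On the glycolysis list 10 of 30 rose and 3 fell, 13 and 3 when adjusted over the list alone (median 1.1, camera adjusted p = 0.0116; adjusted p = 0.351 with an estimated correlation). It was not called under library totals (camera adjusted p = 0.0914). Among glycolysis members pfkpa, a phosphofructokinase gene, rose from 1.48 ± 0.899 to 37.2 ± 19.6 CPM and hk1 from 1.2 ± 0.166 to 5.91 ± 1.74, gapdhs rose from 12.8 ± 2.81 to 59.4 ± 8.36, and gapdh fell from 3940 ± 498 to 755 ± 283 (edgeR adjusted p = 0.00181, 0.00347, 0.00193 and 0.00181). The gluconeogenic gene fbp1b fell from 588 ± 55.1 to 136 ± 36.9 and the fatty acid desaturase gene fads2 from 2140 ± 341 to 240 ± 85.4 (edgeR adjusted p = 0.00412 and 0.0018). Of 32 clock genes 4 rose and 12 fell, 7 and 16 when adjusted over the list alone. The list was lower (median -0.71, camera adjusted p = 0.00189; adjusted p = 0.443 with an estimated correlation) but its median was 0.311 under library totals, where that of all genes was 1.11.

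Of the Nrf2 list 5 of 33 members rose and 1 fell, 8 and 2 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.269). The thioredoxin gene txn rose 8.14-fold and slc7a11 from 0.0754 ± 0.0945 to 15.1 ± 5.57 CPM (edgeR adjusted p = 0.00193 and 0.00257). On the xenobiotic metabolism list 4 of 53 rose and 8 fell, 7 and 14 when adjusted over the list alone, again without a list call (camera adjusted p = 0.246). The P450 gene cyp3c3 rose from 1.88 ± 1.02 to 98.7 ± 56.8 CPM and cyp1a fell 3.64-fold (edgeR adjusted p = 0.0103 and 0.00404). The clock genes dbpb and bhlhe41 fell 6.9-fold and 7.47-fold, and per2 stood 6.77-fold higher (edgeR adjusted p = 0.00181, 0.00193 and 0.000934). Among single genes, esm1 rose from 0.807 ± 0.321 to 907 ± 331 CPM (edgeR adjusted p = 0.00157), and lepa was at least 1400-fold higher by the same floor.

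The count of 2241 became 1370 and 1113 without DMSO replicates 1 and 2, and 1017, 1474 and 1129 without TDCIPP+DOX replicates 1, 2 and 3. DESeq2 called 3453 and library totals gave 6966 higher and 305 lower. Of 23 named genes that passed, 21 passed without any 1 library. The others were dusp6 and cxcl8a.

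TDCIPP+DOX against TDCIPP shows the effect of DOX in fish given TDCIPP. Here 388 genes rose and 413 fell, with 3438 at an unadjusted p under 0.05. The RAS-MAPK list had 12 of 34 members up and 0 down, 20 up when adjusted over the list alone (median 1.64, camera adjusted p = 1.63e-12; adjusted p = 0.127 with an estimated correlation). The ERK pathway inhibitor gene spry4 rose from 4.36 ± 1.49 to 77.9 ± 31.5 CPM, dusp4 from 1.15 ± 0.705 to 31.4 ± 8.84 and dusp6 from 14.8 ± 2.52 to 99.8 ± 45.7 (edgeR adjusted p = 0.00319, 0.00319 and 0.00976), and esm1 and pltp rose by 10.94 ± 1.05 and 10.61 ± 1.36 on the log2 scale (edgeR adjusted p = 0.00257 and 0.00543). On the ribosome biogenesis list 19 of 52 fell, 44 when adjusted over the list alone (median -1.08, camera adjusted p = 3.43e-27; adjusted p = 0.337 with an estimated correlation), with ddx21 and pno1, a factor of the small subunit, at 4.35-fold and 2.91-fold lower (edgeR adjusted p = 0.00319 and 0.00689). On the oestrogen response list 4 of 15 fell, 6 when adjusted over the list alone (median -1.21, camera adjusted p = 1.58e-06; adjusted p = 0.215 with an estimated correlation), with vtg1 3.76-fold and vtg2 3.77-fold lower (edgeR adjusted p = 0.046 and 0.0314). Among genes of proteins that hepatocytes secrete, the antitrypsin gene serpina1l rose from 2930 ± 1000 to 16700 ± 3440 CPM, apoeb, an apolipoprotein E gene, from 211 ± 15.4 to 1070 ± 206, and the clotting factor gene f9b from 92 ± 30.6 to 317 ± 37 (edgeR adjusted p = 0.0149, 0.0087 and 0.0272). Of the hepatocyte list 5 of 33 markers rose and 0 fell, 9 and 6 when adjusted over the list alone and 7 and 3 in DESeq2. That list was not called (camera adjusted p = 0.148). On the handling stress and heat shock list 2 of 25 rose, 6 when adjusted over the list alone (median 1.54, camera adjusted p = 1.89e-05; adjusted p = 0.337 with an estimated correlation), with the chaperone partner gene bag3 up from 3.83 ± 0.83 to 20.3 ± 1.89 CPM (edgeR adjusted p = 0.0126). The thioredoxin gene txn rose 6.57-fold, keap1a fell 3.05-fold and eif4ebp3 fell 8.03-fold (edgeR adjusted p = 0.00697, 0.00543 and 0.00231). The desaturase gene fads2 fell from 1710 ± 575 to 240 ± 85.4 CPM and the clock gene cry2 from 16.2 ± 2.07 to 6.58 ± 0.762 (edgeR adjusted p = 0.00543 and 0.024).

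The count of 801 became 127 and 191 without TDCIPP replicates 2 and 3, and 193, 273 and 128 without TDCIPP+DOX replicates 1, 2 and 3. DESeq2 called 1638 and library totals gave 2534 higher and 190 lower. Of 18 named genes that passed, 10 passed without any 1 library. The other 8 were dusp6, vtg1, vtg2, serpina1l, apoeb, f9b, bag3 and cry2.

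The interaction asks whether TDCIPP acted differently with DOX than without it. Of 19160 genes, 3 were more positive with DOX and 2 more negative. The clock gene per2 (ENSDARG00000034503) stood at 2.23 ± 0.152 CPM in DMSO, 9.94 ± 1.95 in TDCIPP, 32.4 ± 8.08 in DOX and 15.1 ± 0.29 in TDCIPP+DOX, so it was higher with TDCIPP in the groups without DOX and lower with TDCIPP in the groups with DOX (log2 difference -3.25 ± 0.31, edgeR adjusted p = 0.00788). PLEKHH3, which codes for a pleckstrin homology domain protein, stood at 73.7 ± 23.3, 30.8 ± 2.48, 35.6 ± 6.91 and 98 ± 22 CPM in the same order (2.72 ± 0.37, edgeR adjusted p = 0.0469). The somatostatin gene sst1.1, a marker of pancreatic islets, also passed at levels of at most 1.56 ± 1.07 CPM in any group, as did si:dkey-22f5.9 (2.67 ± 0.34) and Novel00094 (-3.5 ± 0.45), both outside the naming rule (edgeR adjusted p = 0.0469 for each of the 3). An unadjusted p under 0.05 was met by 2457 genes, and DESeq2 called 278. The count of 5 became 0 without DMSO replicate 2 or 3 or any 1 TDCIPP+DOX library, 1 without any 1 TDCIPP library, 3 and 2 without DOX replicates 1 and 2, 10 without DMSO replicate 1, 16 without the filter and 0 without the 4 libraries with ovary or intestine markers. With the replicate number as a block it was 3, of which 1 was among the 5.

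**Figure D3:**
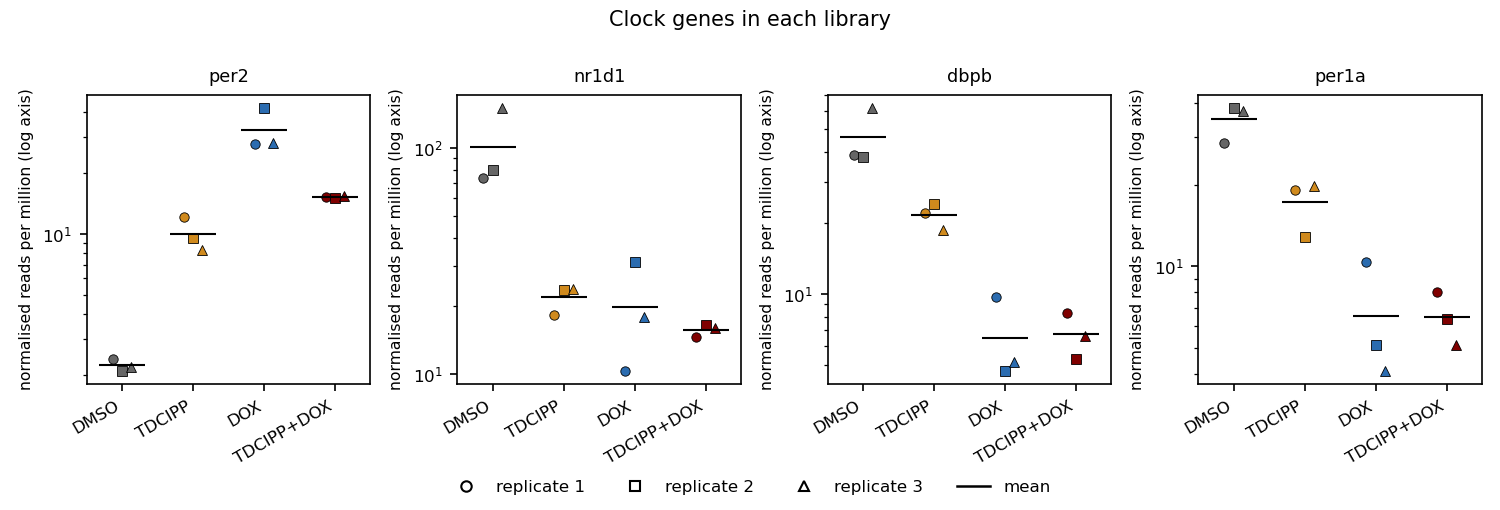
Levels of 4 clock genes in each library, as TMM-scaled CPM on log axes. Points are libraries and bars are group means. The DMSO libraries held the lowest per2 (2.1 to 2.4) and the highest nr1d1 (73.7 to 150) of the 12.

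Over all 19160 genes, the fold changes of TDCIPP without and with DOX correlated weakly (Pearson's r = 0.06, Spearman's rho = 0.09; across genes, which are not independent replicates). Computed on group means of log2 CPM the r was 0.19, and 21 of 100 relabellings of the libraries gave an r as large in size. The fold changes of DOX without and with TDCIPP, which share no library, had r = 0.16 and rho = 0.2. On group means the r was 0.33, which 1 of 100 relabellings, the real one, reached, and the highest other rounds to 0.33 too. The relabellings exchange libraries only within each of the 2 comparisons correlated. Among the 1315 genes changed by DOX without TDCIPP, 1143 had the same direction with TDCIPP (r = 0.72, rho = 0.71). Without DOX replicate 3 the first r was 0.23 and the second 0.26, without TDCIPP+DOX replicate 3 the second was 0.27, and without DMSO replicate 3 the first was 0.21. Without DMSO replicate 1, TDCIPP replicate 1 or TDCIPP replicate 3 the first r was -0.004, -0.019 and -0.027. The second lay at 0.07 without DOX replicate 1 and 0.09 without TDCIPP+DOX replicate 1, and at 0.06 without the filter on low counts.

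The authors' deposited table holds their own calls for 4 of these comparisons. It calls 66 genes for TDCIPP against DMSO, 194 for DOX against DMSO, 34 for TDCIPP+DOX against DOX and 1356 for TDCIPP+DOX against DMSO. Of these, 8, 163, 22 and 1124 also passed here, and each of those tested here had the same direction as in the authors' deposited table.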

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

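The splits of the libraries were planned. The tests of ovary RNA, intestine RNA, neutrophil number, clock phase and hour of collection were chosen only after the results were seen.

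The difference between libraries with and without TDCIPP was itself different with DOX than without it, by the interaction test, for 5 genes: per2 (log2 difference -3.25), sst1.1 (11.74), PLEKHH3 (2.72), si:dkey-22f5.9 (2.67) and Novel00094 (-3.5). The other splits, 50 in all with the real one, gave at most 0 genes past edgeR's test against the real 5 (1 of 50 splits as large; 2457 genes at an unadjusted p under 0.05 and 278 in DESeq2). These splits mix all 4 groups, so the changes with TDCIPP and with DOX enter their spread. They say nothing on how many genes chance gives for the interaction, which stays open.

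By the same test 16 lists differed. Lists of cells had median log2 differences of 0.99 (erythroid), 2.23 (exocrine pancreas), 5.76 (endocrine pancreas), 6.05 (intestine), 0.67 (biliary), 1.5 (stellate and fibroblast), 0.81 (endothelial) and 0.37 (hepatocyte). Lists of pathways had 2.02 (interferon), 1.13 (RAS-MAPK), 0.35 (fatty acid oxidation), -2.48 (cell cycle), -2.44 (sterol synthesis), -0.94 (fatty acid synthesis), -0.89 (ER stress) and -0.92 (ribosome biogenesis). The same mixed splits gave up to 18 lists, and 3 of 50 gave at least 16. All 16 lost the call with an estimated correlation.

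Leaving out 1 library ended the call or moved the median over 1.5 times for each of these lists except endocrine pancreas, endothelial, interferon and ribosome biogenesis. Without DOX replicate 3 the cell cycle median was -0.18, biliary 0.44, hepatocyte 0.14, erythroid 0.63 and fatty acid oxidation 0.22, and these 5 were not called (camera adjusted p = 0.325, 0.157, 0.268, 0.331 and 0.325). Without TDCIPP+DOX replicate 3 the intestine median was 2.07, fatty acid synthesis -0.81 and fatty acid oxidation 0.29, not called (camera adjusted p = 0.122, 0.0758 and 0.0596), RAS-MAPK 0.32 and biliary 0.42. Without TDCIPP replicate 1 ER stress was 0.02, fatty acid synthesis -0.46 and erythroid 0.75, not called (camera adjusted p = 0.559, 0.0676 and 0.0773), and sterol synthesis -0.87. Without DMSO replicate 3 intestine was 2.25 and erythroid 0.57, not called (camera adjusted p = 0.082 and 0.126), exocrine pancreas 1.05 and stellate and fibroblast 1. Without DOX replicate 2 ER stress was -0.74 and fatty acid synthesis -0.56, not called (camera adjusted p = 0.101 and 0.196). Without DOX replicate 1 these 2 were -0.84 and -0.92, not called (camera adjusted p = 0.0524 and 0.07), exocrine pancreas 4.02, biliary 1.03 and hepatocyte 0.7. Without TDCIPP+DOX replicate 2 erythroid was 0.49 and fatty acid oxidation 0.28, and without TDCIPP+DOX replicate 1 erythroid was 0.9, none of them called (camera adjusted p = 0.199, 0.141 and 0.0531). In the latter fit exocrine pancreas was 1.11. Without DMSO replicate 1 RAS-MAPK was 0.64, and fatty acid synthesis (-0.93) and oxidation (0.3) were not called (camera adjusted p = 0.0656 and 0.0592), nor was synthesis without DMSO replicate 2 (-0.9, camera adjusted p = 0.0657).

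Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The other splits put libraries of both groups on each side, so the difference between the groups enters their spread. Their counts are therefore no measure of what chance gives. The real split gave 8, 1315, 403, 2241 and 801 genes (TDCIPP against DMSO, DOX against DMSO, TDCIPP+DOX against DOX, against DMSO and against TDCIPP) and the highest other split 0, 0, 1, 0 and 0, so 1 of 10 splits was as large in each. For lists the real split gave 13, 15, 25, 11 and 7 and the highest other 18, 18, 21, 15 and 19, and 4, 2, 1, 7 and 10 of 10 splits were as large.

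The cell cycle list was higher in DOX than in DMSO, with a median of 2.79. RNA of ovary in DOX replicate 3 is a candidate source for part of it, since the median was 0.46 without that library, all 14 oocyte markers were highest in it (buc at 205.21 CPM), and the camera adjusted p without it was 0.0618. Without that library 8 of 62 members still passed edgeR's test, so a rise in part of the list stays open. The list was also higher than in DMSO in TDCIPP (median 1.1, camera adjusted p = 2.45e-07) and TDCIPP+DOX (median 1.2, camera adjusted p = 4.75e-05), and DOX replicate 3 is in neither comparison. Its per-library means lay between -0.29 and 0.52 in those 2 groups and at -0.68, -1.23 and -1.02 in DMSO. The oocyte markers stood higher in TDCIPP as well, at 0.47, 1.61 and 0.59 against 0.41, -1.18 and -0.25 in DMSO. TDCIPP replicate 2 was the highest and DMSO replicate 2 the lowest of these 6 libraries for both sets. In TDCIPP+DOX the oocyte markers stood at 0.49, -0.27 and -2.64 and the cell cycle list at 0.37, 0.12 and 0.47. Ovary RNA was not tested for these 2 groups and stays open in TDCIPP. All 3 TDCIPP+DOX libraries lay above every DMSO library on the cell cycle list. On the oocyte markers replicate 3 lay below every DMSO library, which argues against ovary RNA as the source of the higher list in that library alone. Replicate 2, at -0.27, was level with DMSO replicate 3, at -0.25, and replicate 1 lay above every DMSO library. Ovary RNA stays open for replicates 1 and 2. In TDCIPP+DOX against DOX the median was -1.5 (camera adjusted p = 0.155), and 1.02 without DOX replicate 3 (camera adjusted p = 4.97e-06). Responses to DOX or TDCIPP, which the design names, stay open and untested.

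The inflammatory list was higher with TDCIPP, by 1.4 on the mean of log2 CPM both without and with DOX. RNA of intestine is argued against: the slope of the inflammatory list on the intestine list within groups gives a difference of 0 (SE 0.03) without DOX and -0.01 (SE 0.17) with DOX. More neutrophils may account for part, since the slope on the neutrophil list gives 0.52 (SE 0.22) without DOX and 0.44 (SE 0.18) with it, which within 2 SE spans 0.7, so neutrophil number and signalling in other cells cannot be told apart. The inflammatory list shares 0 genes with the neutrophil list. With DOX 12 of the 13 cell type lists were higher with TDCIPP, so a change in the share of several cell types stays open there and was not tested. A response to TDCIPP, which the design names, also stays open.

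Clock genes differed between DMSO and both groups with DOX, and moved the same way on balance in TDCIPP. The 3 comparisons share the same 3 DMSO libraries, so their agreement may come in part from those libraries. Genes driven through E-boxes (13 members) had median log2 fold changes against DMSO of -1.01 in TDCIPP, -1.52 in DOX and -1.51 in TDCIPP+DOX. Genes repressed by REV-ERB (8 members) had 0.61, 1.1 and 1.06. The 2 sets lay 1.62, 2.62 and 2.57 apart, which is consistent with another clock phase in both groups with DOX. In DOX 8 of the 13 fell and 1 rose past edgeR's test, and 4 of the 8 rose. In TDCIPP+DOX 8 of the 13 fell past the test. Of the 8 repressed by REV-ERB only 1 rose past it there and 2 were lower, so that side rests mostly on its median. The gene per2 is in neither set. In TDCIPP 12 of the 13 were lower and 7 of the 8 higher, but 0 of the 13 and 0 of the 8 passed edgeR's test. Of the 32 clock genes per2 alone passed there, 2 were higher and 9 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 4 lower. The clock list was not called in TDCIPP (camera adjusted p = 0.106), except without DMSO replicate 1 or 2 (camera adjusted p = 0.0161 and 0.0398), so another phase there rests on the medians. Another hour of collection cannot be told apart from an effect of the treatments for any of the 3 groups, since 0 labels give an hour. An effect of DOX or TDCIPP on the clock stays open and untested.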

How the results depend on the processing

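Library totals and the fit without the 4 libraries with ovary or intestine markers were added after seeing the data; the cause of the changes below was not tested, except that leaving out libraries lowers the number fitted. Of the alternative values of named genes, 1207 kept direction and side of the threshold, 308 kept direction but no longer passed, 28 passed anew and 3 reversed; of list values 1017 kept both, 104 lost the call and 3 reversed. Leaving out each library gave these ranges of genes past the threshold: 0 to 18 (TDCIPP against DMSO), 209 to 1189 (DOX against DMSO), 0 to 476 (TDCIPP+DOX against DOX), 1017 to 1531 (against DMSO), 127 to 609 (against TDCIPP) and 0 to 10 (interaction). Lists called ranged over 14 to 19, 10 to 19, 17 to 24, 12 to 16, 10 to 12 and 12 to 18 in that order. The r of the TDCIPP effects ranged from -0.027 to 0.227 and that of the DOX effects from 0.072 to 0.268.

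In the same order of comparisons, no filter gave 17, 822, 143, 1788, 598 and 16 genes, the replicate block 13, 986, 256, 2060, 727 and 3, library totals 6, 5033, 142, 7271, 2724 and 4, the fit without the 4 libraries 0, 684, 57, 2306, 844 and 0, and DESeq2 414, 2636, 2102, 3453, 1638 and 278. Only the libraries compared gave 11, 97, 0, 3084 and 1092. At a log2 fold change of at least 1 there were 8, 1090, 360, 1893, 730 and 5. Beside each 0 from edgeR stand the DESeq2 counts here and 1920, 4675 and 2457 genes at an unadjusted p under 0.05 with all libraries. Camera with an estimated correlation called 0 lists in each comparison, fry 4, 4, 8, 11, 4 and 1, and camera without the 4 libraries 11 for TDCIPP+DOX against TDCIPP. Over the genes past the threshold the r was -0.099 for TDCIPP and 0.718 for DOX, and the r for DOX was 0.06 with no filter. The first r was -0.004, -0.019 and -0.027 without DMSO replicate 1, TDCIPP replicate 1 and TDCIPP replicate 3. The gene mpx in TDCIPP against DMSO reversed to -0.005 without TDCIPP replicate 2 (highest 1.577 with 1 library left out). The gene ccna2 in DOX against DMSO reversed to -0.837 without the 4 libraries and -0.885 without DOX replicate 3 (highest 3.909 with 1 library left out), the hepatocyte list in TDCIPP+DOX against DOX was 0.00346 and 0.0481 in the same fits, where camera's direction reversed (highest 0.461 with 1 library left out), and the intestine list of the interaction was 0.214 without the 4 libraries, likewise with camera's direction reversed. Of 18 pairs of libraries with the same replicate number 2 correlated over 0.1, so the numbers were not taken as pairs.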

Other observations

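The values below were chosen after the data were examined. Lists not described above moved in some comparisons, and not every list called is printed. In TDCIPP against DMSO the Toll-like receptor and complement lists were higher (medians 0.6 and 0.43, camera adjusted p = 0.00171 and 0.0109). The ribosome biogenesis and oestrogen response lists were lower there (-0.34 and -0.67, camera adjusted p = 1.49e-05 and 0.0109). Leaving out 1 library ended the call of complement, ribosome biogenesis (median 0.04 without DMSO replicate 2) and oestrogen response. The Toll-like receptor median was 0.19 without TDCIPP replicate 3. The handling stress and heat shock list had 5 of 25 members up and 2 down in DOX against DMSO (6 and 3 when adjusted over the list alone) and was not called (camera adjusted p = 0.152). The p53 and apoptosis list had 3 of 30 up and 3 down there (4 and 5 when adjusted over the list alone; camera adjusted p = 0.396). In TDCIPP+DOX against TDCIPP the interferon list had a median of 1.46 (camera adjusted p = 2.36e-06; adjusted p = 0.535 with an estimated correlation), with 0 of 32 past edgeR's test, 19 higher and 1 lower at an unadjusted p under 0.05, 14 higher when adjusted over the list alone and 11 in DESeq2. Without TDCIPP+DOX replicate 3 that median was 0.69. In TDCIPP+DOX against DMSO 2 of 32 members of the gluconeogenesis and amino acid catabolism list rose and 9 fell, 2 and 11 when adjusted over the list alone (median -0.54, camera adjusted p = 0.0007, or 0.504 with an estimated correlation). The list's median was 0.483 under library totals, where that of all genes was 1.11.

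The glucocorticoid-responsive gene klf9, also read with the clock genes, stood at 68 ± 34.7 CPM in DMSO (n = 3 in each group), 7.39 ± 1.79 in TDCIPP, 4.82 ± 2.62 in DOX and 16.3 ± 7.47 in TDCIPP+DOX. The gene tsc22d3, also glucocorticoid-responsive, stood at 463 ± 253, 62.7 ± 3.6, 110 ± 65 and 182 ± 20.6 in the same order, and glula at 149 ± 73.5, 9.41 ± 5.34, 16.2 ± 1.94 and 19.2 ± 4.16. The first 3 components of a principal component analysis of all genes took 22.1%, 20.5% and 15.3% of the variance.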
